A study of Rhipicephalus microplus with 12 samples.

How the data were processed

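Tissue RNA of *Rhipicephalus microplus* was compared with a common reference pool on arrays of 2 colours, with the tissue in Cy5 and the pool in Cy3 on all 12 arrays, per the labels. The deposited value table holds 1 log2 ratio per probe and array, for 13459 probes. The authors used limma, per the submitters' processing notes, and its version, the background correction and the normalization between or within arrays are not given in the sources used here. The log2 scale follows from the deposited tables, since differences of tissue means equal the authors' log2 fold changes and their linear fold is the corresponding power. The direction of each ratio is likely tissue over pool, because the labels put the tissue in Cy5 and limma forms red over green. Medians of the arrays differed (-0.05 to 0.39), so the deposited values were not centred on a common median. Spot intensities were not used here, so no filter on dim spots was applied and levels near background cannot be marked.

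The authors' deposited comparison tables give, per the file headers, a log2 fold change, an adjusted p-value and a fold (a ratio) per probe. They list 13459 probe identifiers, of which 10695 have values and 2764 (20.5%) are empty. The value table names its lines by number only. Each number was therefore paired with an identifier through the authors' log2 fold changes of midgut against ovary and of midgut against salivary gland. Both had to be equal, within 2e-08, to differences of tissue means over all arrays or over part of them. All 10695 identifiers found a line, 7129 with all 12 arrays and 3566 with part of them, with 0 ambiguous pairs. Decoys, which joined the midgut minus ovary value of a probe to the midgut minus salivary gland value of another, found 3. The remaining 2764 lines have no name here. Of the identifiers, 9121 start with Contig and 4338 do not. None was in the RefSeq table (0 matches), and 0 matched the 24 gene lists, cell type markers included, that were fixed before the data were examined, so no list was tested.

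The arrays of a biological replicate were averaged (avearrays), a model of tissue means was fitted to the 6 replicates with limma 3.58.1 in R 4.3.3 (lmFit, eBayes), and p-values were adjusted by Benjamini-Hochberg over all probes of a comparison. The threshold was an adjusted p of 0.05 with no fold limit, and the fit left 3 residual degrees of freedom. An exact permutation test of 2 against 2 samples cannot go below p = 0.33, so no single-probe permutation test was run. Named probes followed a rule fixed before the data were examined: as the files pair no descriptions with probes, the 2 probes with the highest and the 2 with the lowest difference per comparison, among probes with an identifier, past the threshold and with replicates that do not overlap. The probes tagged for TATA-binding protein and ribosomal protein L4 were added after the files had been seen.

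The procedure was tested on simulated data for midgut minus ovary with 13459 probes, 200 of them changed. It recovered 12.5% of changes of 1 on the log2 scale with 8 false calls, and 96.5% of changes of 2 with 7 false calls. With 5467 probes changed by the measured folds, 91.6% were recovered and 3.93% of calls were false. These 5467 were the probes called in the measured data, and all others were left unchanged, so a high recovery was largely built in. The simulated noise was independent between probes and samples, with no component shared by arrays and no slide effect. These shares therefore need not hold for the measured data.

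Midgut and salivary gland arrays lay on 1 slide and ovary arrays on another, per the labels, so a slide term cannot be fitted for ovary. Alternatives covered the handling of repeat arrays, normalization, centring, the samples in the fit, a replicate block, thresholds, moderation, contig averaging and leaving out each replicate. Further alternatives, chosen after seeing the data, left out or modelled 3 arrays, exchanged the ovary repeats, or followed the probes and spots the authors kept. Figures were drawn with matplotlib 3.10.9, and tables were joined with pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15.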

Results

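RNA of midgut, ovary and salivary gland from adult females of the cattle tick *Rhipicephalus microplus*, harvested on day 20 of infestation, was hybridised on 12 arrays of 2 colours. Every array carried a tissue in Cy5 and a common reference pool of ticks from several feeding days and of dissected tissues in Cy3. Each of the 3 tissues had 2 biological replicates with 2 arrays per replicate, and the arrays of a replicate were averaged, so that n = 2 per tissue. The labels do not say how many animals a replicate holds or whether replicates came from separate cattle, so the p-values measure only the spread between these samples. The values were log2 ratios for 13459 probes with 0 missing values, and their direction is likely tissue over pool, from the dyes in the labels. All 12 arrays were skewed to low ratios (skewness -1.81 to -0.70), with lowest ratios of -7.71 to -4.68 and highest of 2.88 to 4.72. As the pool held dissected tissues, a tissue can exceed it only to a limited extent but can fall far below it. The skew thus argues against pool over tissue. No array was dye-swapped, so a dye bias equal on all arrays cancels in differences between tissues but not in ratios to the pool. Whether it was equal on the separate slide of the ovary arrays was not tested. The number of arrays limits the precision, and the median standard error of a difference between tissues was 0.23 on the log2 scale. The probes carry contig and sequence identifiers that the files do not pair with gene descriptions, so probes are named by identifier and no gene function is given.

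The arrays separated by tissue. Across probes, which are not independent replicates, Pearson's r was 0.305 to 0.598 between arrays of different tissues, 0.775 to 0.942 between arrays of different replicates of a tissue and 0.812 to 0.948 between arrays of the same replicate. After averaging, the replicates correlated with r of 0.917 in midgut, 0.953 in ovary and 0.83 in salivary gland. The first principal component, with 45.9% of the variance, set the 4 ovary arrays apart from the other 8. The third component, with 16.3%, set apart 3 arrays, namely the repeat array of midgut replicate 2, the first array of ovary replicate 1 and the repeat array of ovary replicate 2, and counts without these arrays are given beside the counts with all arrays. The median log2 ratio was -0.05 on that midgut array against 0.26 to 0.31 on the other midgut arrays, and -0.03 on both of those ovary arrays against 0.34 and 0.39 on the other ovary arrays. The salivary gland arrays had medians of 0.08 to 0.14. Each averaged ovary replicate held 1 of the ovary arrays set apart and 1 of the others. What the arrays set apart share thus entered both ovary averages, and the r of 0.953 does not reflect it. Nor does the ovary part of the standard errors. Between arrays of the same ovary replicate, r was only 0.813 and 0.812.

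**Figure D1:**
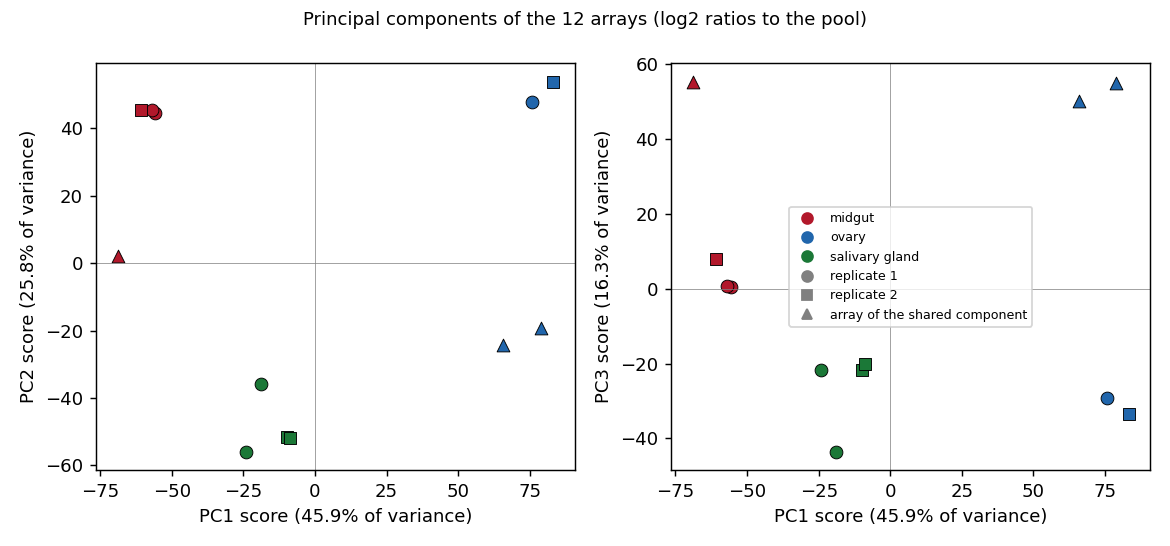
Scores of the 12 arrays on principal components 1 and 2 (left) and 1 and 3 (right) of the log2 ratios, in arbitrary units, with colour for tissue and shape for replicate. Triangles mark the 3 arrays that lie at scores of 50.23 to 55.31 on component 3, above all other arrays.

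The first comparison asked which transcripts differ between the midgut, the site of blood meal digestion, and the ovary. Probe Contig5935 stood 131-fold higher in midgut (log2 difference 7.03, SE 0.30, limma adjusted p = 1.95e-05), with log2 ratios of 2.77 ± 0.09 in midgut and -4.26 ± 0.32 in ovary (SD, n = 2 each). Contig158 was 125-fold higher in midgut (6.97, SE 0.26). The folds depended on the normalization: with quantile and scale normalization the log2 difference was 5.91 and 6.04 for Contig5935 and 5.80 and 5.99 for Contig158, and with scale normalization it was -5.75 for Contig6410 and -5.64 for Contig337. In the other direction, Contig6410 had a midgut minus ovary difference of -6.64 (SE 0.23, limma adjusted p = 1.14e-05), a fold of 99.5 in favour of ovary, and Contig337 had -6.51 (SE 0.34). For both ovary probes the salivary gland lay between the other tissues, with log2 ratios of -1.38 ± 0.27 and -1.30 ± 0.72 (SD, n = 2).

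Of the 13459 probes, 5467 (40.6%) passed an adjusted p of 0.05 in limma for midgut against ovary, 3008 higher in midgut and 2459 higher in ovary. The difference reached at least 8-fold for 240 probes higher in midgut and 191 higher in ovary, and at least 32-fold for 75 and 30. The probe tagged for the TATA-binding protein, a general transcription factor, gave -0.72 (SE 0.19, limma adjusted p = 0.0195), that is, lower in midgut, a call lost with first or repeat arrays only, with a 2-fold limit, at an adjusted p of 0.01 and without midgut replicate 2 (-0.67), ovary replicate 1 (-0.80) or ovary replicate 2 (-0.64). The probe tagged for ribosomal protein L4 gave 0.36 (SE 0.19, limma adjusted p = 0.18) and did not pass, although it passed with the replicate as a random block and has an adjusted p of 0.00772 in the authors' deposited table. Ovary arrays lay on a slide of their own, so slide and ovary cannot be told apart here. Without the 3 arrays above, 6846 probes passed and the share higher in midgut changed from 55.0% to 40.7%, and without ovary replicate 2 the count was 3463.

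Midgut and salivary gland, which share a slide, were compared next. Among probes with an identifier, Contig5935 again had the highest difference in favour of midgut (5.09, SE 0.30, 34.1-fold, limma adjusted p = 0.000187), followed by Contig5086 at 4.95 (SE 0.23, 31.0-fold). Contig5329 was higher in salivary gland, with a midgut minus salivary gland difference of -5.76 (SE 0.36, 54.0-fold, limma adjusted p = 0.000202), and CV452616 gave -5.30 (SE 0.44, 39.5-fold). Contig5329 had log2 ratios of -3.31 ± 0.08 in midgut, -3.90 ± 0.69 in ovary and 2.45 ± 0.49 in salivary gland (SD, n = 2 each). The salivary gland ratio of CV452616 had a wide spread, 1.88 ± 1.06 (SD, n = 2), and its difference was -6.06 without salivary gland replicate 1 and -4.55 without replicate 2. Quantile normalization gave 5.74 for Contig5935 and 5.57 for Contig5086.

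This contrast had the fewest probes past the threshold, 2686 of 13459 (20.0%), of which 1256 were higher in midgut and 1430 in salivary gland. At least 8-fold differences numbered 147 in favour of midgut and 91 in favour of salivary gland. The probes tagged for TATA-binding protein (0.17, limma adjusted p = 0.558) and ribosomal protein L4 (-0.09, limma adjusted p = 0.766) did not pass. Centring each array on its median gave 993 higher in midgut and 1764 in salivary gland, and leaving out the 3 arrays gave 2066 and 1499, so no majority direction is given. Counts were 1698 without salivary gland replicate 1, 1693 without salivary gland replicate 2, and 4190 when the 12 arrays entered with the replicate as a random block.

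The third comparison set ovary against salivary gland. Read as tissue over pool, salivary gland probes showed the wider range, and read as pool over tissue, ovary probes would. CV452616 had an ovary minus salivary gland difference of -6.67 (SE 0.44, 101.5-fold, limma adjusted p = 0.000594) and Contig5338 one of -6.66 (SE 0.27, limma adjusted p = 0.000355). The highest differences in favour of ovary were 3.47 for Contig8884 (SE 0.38, 11.1-fold, limma adjusted p = 0.00119) and 3.35 for Contig2208 (SE 0.19, 10.2-fold). Without salivary gland replicate 1 and without replicate 2, CV452616 gave -7.42 and -5.91, and Contig8884 gave 2.85 and 4.08. With quantile normalization the values were -6.03 for CV452616, 4.08 for Contig8884 and 3.94 for Contig2208. Contig8884 had log2 ratios of 1.89 ± 0.15 in ovary, -1.58 ± 0.87 in salivary gland and -4.49 ± 0.03 in midgut (SD, n = 2 each). At the 30 probes at least 32-fold lower in midgut than in ovary, ovary minus salivary gland had a median of 2.75 and an SD across probes of 0.29.

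Of 13459 probes, 5779 (42.9%) passed for ovary against salivary gland, 2913 higher in ovary and 2866 higher in salivary gland. Of these, 570 were among the probes left empty in the authors' deposited tables, 476 higher in ovary and 94 higher in salivary gland. A fit to only the 10695 probes with values there gave 2672 higher in ovary and 3044 in salivary gland. The balance thus depended on the probes included, and no majority direction is given. Of the 5779 probes, only 7 were at least 8-fold higher in ovary, against 116 at least 8-fold higher in salivary gland. Without the 3 arrays these counts were 14 and 106. The tissues would change places were the ratios pool over tissue. At the 30 probes named above, the median salivary gland level was 12.6% of that in ovary in replicate 1 and 18.3% in replicate 2. Ovary RNA in the salivary gland samples, left open below, would limit how far ovary can exceed salivary gland. The 7 therefore do not count the transcripts particular to ovary. The TATA-binding protein probe was higher in ovary (0.88, SE 0.19, limma adjusted p = 0.0091), a call lost without ovary replicate 2 (0.80) and with a 2-fold limit. The ribosomal protein L4 probe gave -0.45 (SE 0.19, limma adjusted p = 0.0969), which passed with the replicate as a random block and has an adjusted p of 0.00147 in the authors' deposited table. Slide and ovary cannot be told apart in this contrast either. The count was 7968, with 66.4% in place of 50.4% higher in ovary, without the 3 arrays, 3234 without ovary replicate 2 and 3629 without salivary gland replicate 1.

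**Figure D2:**
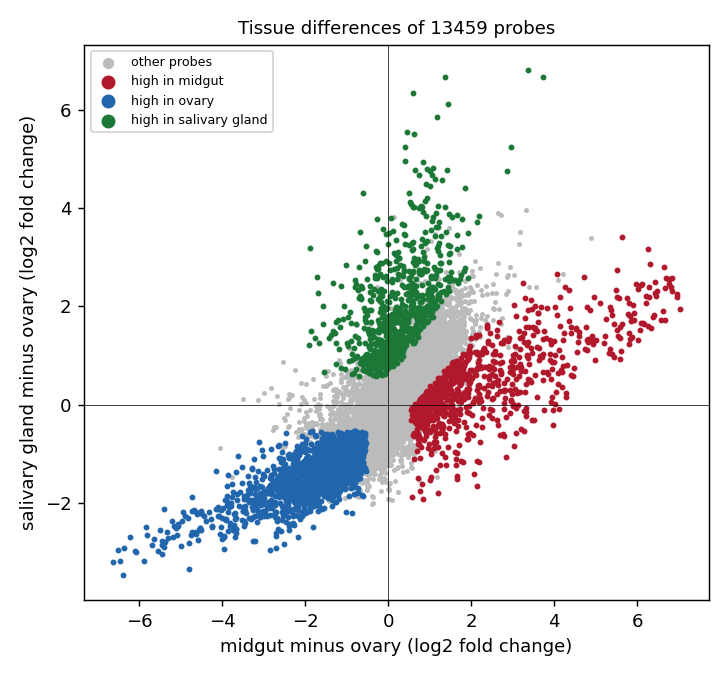
Log2 difference of midgut minus ovary (horizontal) against salivary gland minus ovary (vertical) for each probe, coloured where the probe was higher in a tissue than in both others in limma. Probes high in ovary lie at the lower left and stop at 3.47 below zero on the vertical axis. Probes high in salivary gland reach 6.81 above zero, at a probe without an identifier. Ovary RNA in the salivary gland samples, which stays open, could limit the ovary side.

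Probes higher in a tissue than in both others numbered 825 for midgut, 1865 for ovary and 754 for salivary gland. Independent lists of the same sizes would share 280.7, 532.2 and 304.5 probes. In 20 simulations of unchanged groups the overlap was at most 0, which sets no level for long lists, since almost no probe passes an adjusted threshold without a change. The contrasts behind each count share the arrays of that tissue, and part of the excess may come from that. At least 8-fold over both other tissues were 133 midgut probes, 50 salivary gland probes and 7 ovary probes. Possible ovary RNA in the salivary gland samples limits the reading of the ovary count here too. Were the ratios pool over tissue, such probes would be those at least 8-fold under both others, which numbered 12, 0 and 7 as the values stand. In the low direction, 656 probes were lower in midgut than in both others, 1783 lower in ovary and 328 lower in salivary gland, where independent lists would share 261.3, 640.5 and 271.8. Without the 3 arrays these counts were 700, 1643 and 1134. In total 7721 probes (57.4%) passed in at least 1 comparison and 5738 in none. Counts of high probes without the 3 arrays were 866, 3497 and 795, and 769, 1839 and 729 of these were also high with all arrays. Without ovary replicate 2 the ovary count was 1120. The salivary gland count was 482 without midgut replicate 2 and 490 without salivary gland replicate 1, and the midgut count was 540 without salivary gland replicate 2.

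**Figure D3:**
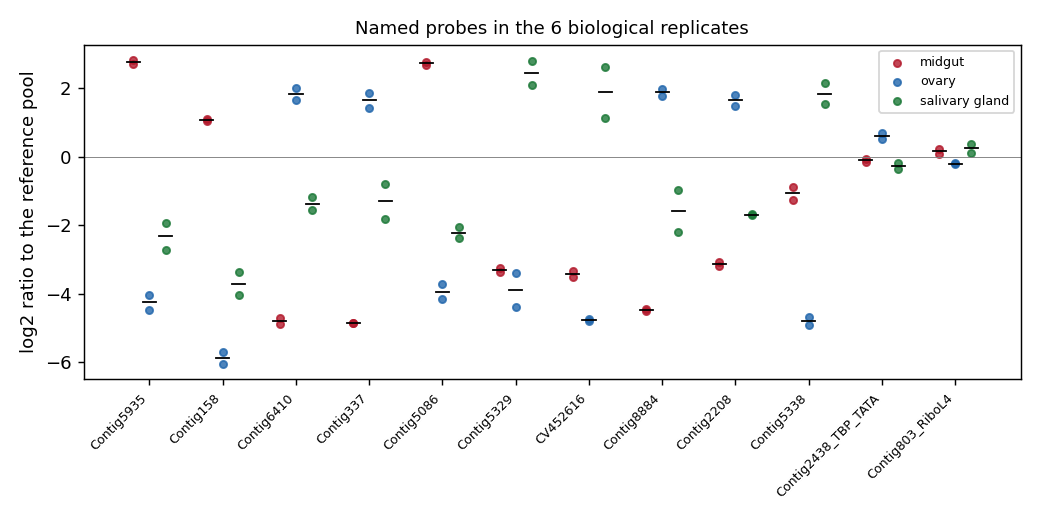
Log2 ratio to the reference pool of the probes named in the text, with a point per biological replicate (n = 2 per tissue) and a line at the mean. Midgut and ovary lie close together for Contig5329 (midgut -3.36 to -3.25, ovary -4.38 to -3.41), and the probes tagged for TATA-binding protein and ribosomal protein L4 stay between -0.36 and 0.69.

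The authors' deposited tables list the same comparisons for 10695 probes. At an adjusted p of 0.05, the authors' deposited table for midgut against ovary holds 6953 probes, that for midgut against salivary gland 4624 and that for ovary against salivary gland 6945. Of the probes past the threshold with averaged arrays that those tables cover, 5094 of 5165, 2412 of 2471 and 5106 of 5209 were also past it there, all in the same direction. Both rest on the same arrays, and identifiers were paired by these fold changes. The shared direction was therefore largely fixed in advance, and the overlap is no independent support for the calls.

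**Figure D4:**
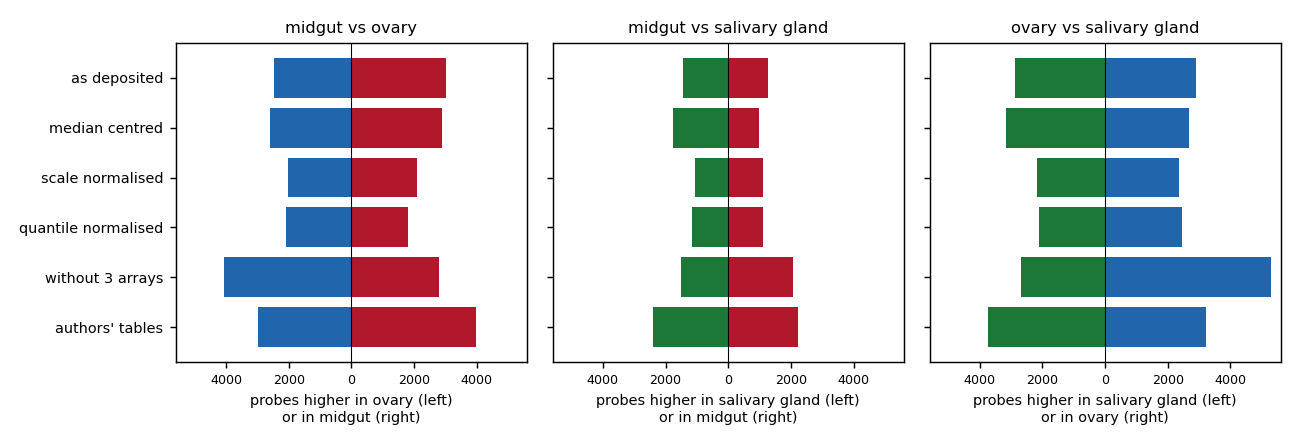
Probes past an adjusted p of 0.05 for each comparison, in limma under several settings and in the authors' deposited tables, with bars to the right for probes higher in the tissue named first and to the left for those higher in the other. Without the 3 arrays the bars shift towards ovary in both ovary comparisons, to 4061 and 5287 probes.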

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

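The tests of the shared component and of crossed labels were chosen only after the result was seen; the test on left-out spots was planned before its result. Among 18 array measures tested, chance alone would mark about 1 in 20. The repeat array of midgut replicate 2 had a median log2 ratio of -0.0478, far from the 0.259 to 0.305 of the other midgut arrays. The first array of salivary gland replicate 1 had a median of 0.140, apart from the 0.0764 to 0.0798 of the other salivary gland arrays.

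The midgut array stood apart together with a pattern in ovary: the first array of replicate 1 correlated with the repeat array of replicate 2 at r = 0.931 across probes, and the remaining ovary pair at 0.942, against 0.813 and 0.812 within replicates. Crossed labels of the ovary repeats would leave only technical spread both ways, equal in size if the technical differences within the array pairs are unrelated. The spread by replicate label was 1.503 times that by first and repeat array (1.314 to 1.705 over 20 parts of the probes, all from the same arrays). A technical component shared by arrays could also make the spreads unequal, so this does not decide on crossed labels. A technical component shared by several arrays is a candidate explanation, as the deviation of the midgut array correlated at r = 0.719 across probes with the split of the ovary arrays. The same 3 arrays stand apart on the third principal component, so this r largely restates that. The deviation also correlated at r = -0.48 with the difference between the arrays of salivary gland replicate 1, so the component may not be limited to the 3 arrays. Regression on the deviation lowered the SD of the ovary split from 0.797 to 0.554, against 0.399 for the split by replicate label. How much of the ovary pattern the component accounts for was not settled. Whether the component is tied to spots the authors left out stays open. The 3 arrays had fewer such spots than the other arrays of their tissues. The counts were 12 against 821 to 1157 in midgut, and 325 and 1 against 974 and 913 in ovary. These counts go with such a tie. The median deviation differed by -0.39 between probes with at least 2 such spots and probes with none, short of the 0.5 set beforehand. In ovary, where no limit was set, the median split was -0.98 at the 528 probes left out on both of the other ovary arrays and -0.16 at the 9336 left out on neither. No biological explanation was tested, since arrays of the same replicate share their RNA.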

How the results depend on the processing

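All alternatives that leave out or model 3 arrays, exchange the ovary repeats, keep only the authors' probes or spots, or treat the 12 arrays as independent were chosen after seeing the data. Where a count of probes past the threshold moved by over 1.5 times, the cause was not tested unless given. A replicate block gave counts of 5342, 2560 and 5681 for midgut against ovary, midgut against salivary gland and ovary against salivary gland. These were within 1.5 times of those without it. Deviations of same-numbered replicates correlated at -0.029, 0.034 and 0.101, but 1 difference per tissue cannot settle pairing. With the replicate as a random block, midgut against salivary gland had 4190 and the high probes of midgut and salivary gland 1297 and 1195. First arrays only gave fewer, 1427 and 3806 for midgut and ovary against salivary gland. High in midgut, ovary and salivary gland were 520, 1238 and 414. Repeat arrays only gave 3580, 1118 and 3408 for the 3 comparisons and 393, 1241 and 295 high probes. A 2-fold limit left 3545 for midgut against ovary, 3566 for ovary against salivary gland and 1122 high in ovary. An adjusted p of 0.01 in limma left 3348, 1222 and 3177, with 442, 1080 and 320 high probes. Leaving out 1 replicate, so that a lone sample is assumed to vary like the other groups, gave 3463 to 5346, 1693 to 2099 and 3234 to 6117 for the comparisons and 540 to 633, 1120 to 1872 and 482 to 632 high probes; the lowest came without ovary replicate 2 (3463, 3234 and 1120), salivary gland replicate 2 (1693 and 540) and midgut replicate 2 (482), and 3629, 1698 and 490 without salivary gland replicate 1. Without the 3 arrays, 3497 probes were high in ovary, and with them as a covariate and a random block there were 4558 for midgut against salivary gland and 1268 high in midgut. With the arrays as independent samples, only the authors' 10695 probes and the left-out spots missing, changed together, midgut against salivary gland had 5332, and 1785 probes were high in midgut and 1426 in salivary gland; averaged arrays with those probes and spots gave 3042. The authors' deposited table for midgut against salivary gland had 4624. Leaving out the 3 arrays moved the median of all probes from 0.04, 0.13 and 0.13 to -0.16, 0.22 and 0.33 in the 3 comparisons. Named probes, chosen by rule as extremes, kept direction and side of the threshold in 276 of 276 values, which that choice largely fixed. In 17 the fold moved by over 1.5 times, under quantile or scale normalization or without a salivary gland replicate. The TATA-binding protein probe lost the threshold for midgut against ovary with first or repeat arrays only, at an adjusted p of 0.01 in limma, with the 2-fold limit, and without midgut replicate 2 or either ovary replicate, and for ovary against salivary gland with the 2-fold limit and without ovary replicate 2. The ribosomal protein L4 probe gained the threshold in both ovary comparisons with the replicate as a random block and with independent arrays, and for ovary against salivary gland also with the covariate. The intensity trend, the filter on dim probes and the gene list alternatives were not run, since no intensities or gene names were used here, nor was the filter on missing values, of which there were 0.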

Other observations

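The tests of the distance between ovary and salivary gland (its spread, the lowest ratio and the correlation of replicates), of paired contig probes, of identifiers starting with GO and of the ovary slide were chosen only after the result was seen, and limits in them were set knowing related values. The tests of the difference between salivary gland replicates, of the probes left empty and of low ovary ratios without 3 arrays had their limits set before the result was seen, the first of them when the replicate difference at the strongest ovary probes was already known.

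Salivary gland took middle values at ovary probes: at the 30 at least 32-fold lower in midgut than in ovary, ovary minus salivary gland had a median of 2.75 with an SD of only 0.29 across probes and a range of 2.12 to 3.47. The lowest ratio that salivary gland arrays can show is argued against, as the median there lay 3.62 above their lowest ratio and midgut had a median of -4.06 at the same probes. Ovary RNA in the salivary gland samples stays open as a candidate explanation, untested by that SD, which is the pattern itself, and by the 161 probes 8-fold to 32-fold lower in midgut, where replicate 2 exceeded replicate 1 by 0.515 more than over all probes, since this compares 1 sample with 1 other. Expression of these probes in salivary gland at levels of their own stays open too, as the replicates correlated at r = 0.198 over the 30 probes (permutation p = 0.305). The probes were chosen by rule from these samples, and no marker list could be used. The 75 probes at least 32-fold lower in ovary than in midgut had a median midgut minus salivary gland of 4.16 with an SD of 0.53. At the 30 probes ovary minus midgut was itself narrow, with an SD of 0.48. Median ovary minus salivary gland rose from 1.07 at probes with ovary minus midgut of 1 to 2 to 2.99 at those of 6 to 7. The distance was thus not constant over all ovary probes.

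Probes named for the same contig with the endings A and B did not change together. Over 58 pairs, midgut minus ovary correlated at r = 0.044 (permutation p = 0.742, adjusted p = 0.742 by Benjamini-Hochberg over 3 comparisons, not limma). This argues against both probes reading 1 transcript only if the identifiers belong to the values. Of 16 pairs with both probes past the threshold, 8 went the same way. Midgut minus salivary gland gave r = 0.12 (permutation p = 0.363, adjusted 0.544) with 4 of 5 such pairs the same way, and ovary minus salivary gland r = -0.27 (permutation p = 0.0392, adjusted 0.118) with 3 of 13. Identifiers shuffled against values stay open, since the order found for the GO probes below (one-sided Fisher exact p = 3.06e-09) covers no Contig probe. Such a shuffle would also touch the identifiers of the Contig probes named in the comparisons. That only 1 probe of a pair reads a transcript, which could hold for probes of opposite strand, stays open: 30 pairs had exactly 1 probe past the threshold, within the 22 to 36 of random pairings, and probe strand was not used here.

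Of 15 probes whose identifier starts with GO, 10 were higher in salivary gland than in both other tissues, against 6.47% of other named probes (one-sided Fisher exact p = 3.06e-09, adjusted p = 7.34e-08 two-sided over 24 tests by Benjamini-Hochberg, not limma), and 10 were so without the 3 arrays. Their median difference was -2.12 for midgut and -3.52 for ovary minus salivary gland.

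Probes left empty in the authors' deposited tables were expected to pass the threshold more often, had they been dropped for unusable spots in a tissue, but the share with at least 1 call was 26.7% against 65.3%, a difference of -38.59 percentage points, so the hypothesis was not borne out in that part. Probes whose only left-out spots were in ovary had a median ovary difference of -0.11 from the other tissues, close to the -0.20 of probes with none left out. Why these probes are empty cannot be told from these values.

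More probes fell at least 8-fold below the pool in ovary (433) than in midgut (246) or salivary gland (70), if the ratios are tissue over pool. At least 8-fold above it were 0, 8 and 0, and without the 3 arrays 159, 9 and 0. Mainly 1 ovary array held such high ratios, the first of replicate 2 with 433 probes. The repeat array of replicate 1 had 58, and the other ovary arrays 1 and 0. The ovary count was 1.76 times the midgut count with all arrays, where slide and ovary cannot be told apart, and 1.589 times without the 3 arrays, which argues against what these 3 arrays carry as the whole cause; a part of the component on other arrays would remain.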
